A study of Homo sapiens with 50 samples.

How the data were processed

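The series holds 50 arrays of human dorsolateral prefrontal cortex, 25 labelled Control and 25 labelled MDD. Per the labels' protocols, ribosomal RNA was removed, the remaining RNA was amplified and labelled with Cy3 by random priming, and each sample was hybridised to 1 array of an lncRNA design with up to 8 arrays per slide. The authors scanned the slides and extracted spot intensities with Agilent Feature Extraction 11.0.1.1, per the file headers and labels. The deposited scanner files give for each spot a background-corrected intensity on a linear scale and also median signal and local background intensities. The deposited files also hold quality flags per spot, which are neither counts nor levels (detection, outlier and saturation flags). The authors' value table holds log2 values after quantile normalization in GeneSpring GX 12.1, per the series' design text. Each of its 50 columns correlated best with the scanner values of its own array (lowest r = 0.995 over probes), the slope against log2 scanner values was 0.985, and column medians were 6.70 to 6.71, so the values are on a log2 scale and not centred per probe. How the table averages spots is not given in the sources used here.

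Groups were taken from sample titles. The main comparison used the log2 of the background-corrected intensity. Spots with an outlier flag (0.228% of spots on the median array) were left out, arrays were quantile-normalized following the authors' method, and spots of 1 probe were averaged. Of 15719 spots per array, 536 were control spots and were left out, as were 60 negative-control probes and 20 custom probes with no stated purpose. No spot was saturated. Of 14843 remaining probes, 13524 were well above background on at least 25 of the 50 arrays and were tested. They comprise 6801 lncRNA probes, 6678 probes of the SEP, SUPERP and TFP families and 45 mRNA probes. A probe was called an lncRNA probe where its identifier contains LNC. The arrays' number limits the precision.

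MDD was compared with control with limma 3.58.1 (lmFit and eBayes, no covariate) in R 4.3.3, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Array-level values were compared with two-sided permutation tests of 100000 resamples (scipy 1.17.1 in Python 3.11.15, or R). Permutation tests of the probe families gave adjusted p of at least 0.204. Functional groups were tested with camera at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry, whose adjusted p was at least 0.150. The test procedure was tested on simulated data with known differences. Tables were handled with pandas 2.3.3 and numpy 2.4.6, robust fits used statmod 1.5.0, and plots were drawn with matplotlib 3.10.9.

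Gene names came from RefSeq accessions on the 50 catalogue probes, all 50 of which matched a RefSeq gene table of assembly GRCh38.p14. That table served only for names, and no coordinates are given. The files pair no other probe with a gene name. Genes were named by a rule fixed before the data were examined. It takes, per probe class, the 6 largest increases and 6 largest decreases past the adjusted threshold, or with too few of those the smallest unadjusted p-values, plus up to 3 tested members of each fixed gene list. Genes from XIST and the Y chromosome are excluded from the rule, which could be applied only to named probes. For unnamed lncRNA probes 2 identifiers per direction are given. Of 25 gene lists fixed in advance, 1 had a named member on the array, so no list reached the 5 members needed for a test. The 5 functional groups of mRNA probes were written later, with the names but not the values in view.

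Slides were inferred from arrays that share a scan time stamp, numbered in scan order, and 4 scan days were numbered likewise. Alternatives fixed before the data were examined were scaling to the 75th percentile, normexp background correction with an offset of 50, the authors' value table, no filter on dim probes, a filter on all 50 arrays, slide as a fixed or a random block, scan day as a block, the subject number as a block, array quality weights, the first principal component as a covariate, and eBayes with trend and robust settings. The normexp alternative used median signals because the files hold no mean signal. Its offset is added before the log2 and shrinks log2 differences, most of all for dim probes. Leaving out slide 4, slide 6 or the array of lowest correlation was added after the data were seen. The closest pair of arrays differed by a median of 0.17 log2 over catalogue probes, against 0.11 between spots of 1 probe on an array. This does not exclude a repeat hybridisation, and each array was counted as 1 sample, as labelled.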

Results

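RNA from human dorsolateral prefrontal cortex, a brain region involved in working memory and the control of behaviour, was profiled on 50 single-colour microarrays. The labels put 25 arrays in a control group and 25 in a group called MDD, each from a separately numbered subject. The array carries probes for long non-coding RNAs (lncRNAs) associated with super-enhancers, which are dense clusters of enhancers near strongly expressed genes. The question addressed was which of these transcripts differ between MDD and control cortex. Most probes are known only by the manufacturer's identifier, so 7753 lncRNA probes are described here as a class. A further 7040 probes belong to identifier families SEP, SUPERP and TFP, whose meaning the files do not give. The genes that could be named are those of 50 catalogue mRNA probes. On average 89.7% ± 4.84 (SD, n = 25) of probes were well above background on control arrays and 89.1% ± 3.93 (SD, n = 25) on MDD arrays. That difference of -0.588 percentage points was within the spread between arrays (two-sided permutation p = 0.638), and it turned to 0.0536 when permuted within slides and to 0.624 without slide 6. The number of arrays limits the precision of every comparison.

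No named mRNA passed the test between MDD and control cortex after adjustment for multiple testing. Of the 45 mRNA probes bright enough to test, 32 had a lower mean in MDD and 13 a higher mean (25 to 33 lower over the alternatives that tested all 45), and 0 passed an adjusted p of 0.05 in limma. At an unadjusted p under 0.05 there were 7 probes, all lower in MDD, where chance would give about 2. That number was 0 without the 1 MDD array of lowest correlation, 0 without slide 4, 1 with the first principal component as a covariate, and 2 with 75th percentile scaling or array quality weights. It was 3 with normexp or with scan day as a block. Adjusted over the mRNA probes alone, 0 passed as well, with a smallest adjusted p of 0.277. The estimates below are therefore given as values and not as changes.

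Lower means in MDD with the smallest unadjusted p-values came from 6 genes of varied function. PPIP5K2, a kinase that makes inositol pyrophosphates, averaged 8.77 ± 0.99 (SD, n = 25) in control and 8.10 ± 1.35 (SD, n = 25) in MDD on the log2 scale. Its difference of -0.67 had a 95% interval of -1.32 to -0.02, and the MDD mean was lower on 6 of the 6 slides that held both groups. MTDH, a membrane protein studied mainly in tumours, differed by -0.43 (95% interval -0.85 to -0.01). SMC6, part of a chromosome-maintenance complex used in DNA repair, differed by -0.42 (95% interval -0.80 to -0.03). ERGIC2, a protein of the compartment between the endoplasmic reticulum and the Golgi, differed by -0.40 (95% interval -0.80 to -0.01). NOC3L, a nucleolar protein, averaged 7.53 ± 0.36 in control and 7.26 ± 0.55 in MDD (SD, n = 25 each). ZNF195, a zinc finger protein, had the smallest unadjusted p of the mRNA probes (0.0332) at a difference of -0.26 (95% interval -0.50 to -0.02). The adjusted p of all 6 was 0.864. With slide as a block their differences ran from -0.81 for PPIP5K2 to -0.27 for ZNF195, and each was lower in MDD on at least 4 of 6 slides. These 6 were picked by their p on the same arrays, so agreement between slides is no separate support for them. Over all alternative settings the difference ran from -0.85 to -0.21 for PPIP5K2, -0.52 to -0.20 for MTDH, -0.52 to -0.12 for SMC6, -0.48 to -0.11 for ERGIC2, -0.30 to -0.17 for NOC3L and -0.27 to -0.17 for ZNF195.

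Higher means in MDD were smaller and less certain. EXO1, an exonuclease of mismatch repair, differed by 0.21 (SE 0.17). POLR2A, the largest subunit of RNA polymerase II, differed by 0.14 (SE 0.21) and was the 1 named member of the gene lists fixed in advance, from the list on super-enhancer machinery. ITGB3BP, a centromere protein, COL13A1, a transmembrane collagen, PIMREG, a mitotic regulator, and CPS1, the first enzyme of the urea cycle, differed by 0.13, 0.13, 0.11 and 0.10. None of these 6 reached an unadjusted p of 0.05, the smallest being 0.222 for EXO1, though ITGB3BP had an unadjusted p of 0.0173 with array quality weights. Over the alternatives the difference ran from 0.066 to 0.32 for EXO1, -0.094 to 0.34 for POLR2A, 0.011 to 0.26 for ITGB3BP, -0.023 to 0.25 for COL13A1, -0.0038 to 0.23 for PIMREG and 0.025 to 0.28 for CPS1. With slide as a block COL13A1, ITGB3BP, CPS1 and EXO1 were at -0.023, 0.011, 0.030 and 0.097, and PIMREG and POLR2A at 0.23 and 0.26. The MDD mean was higher on 6 of 6 slides for EXO1 and on 5 for PIMREG and CPS1. It was higher on 3 slides for COL13A1 and POLR2A and on 2 for ITGB3BP. These 6 were picked on the same arrays too, so agreement between slides is no separate support.

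**Figure D1:**
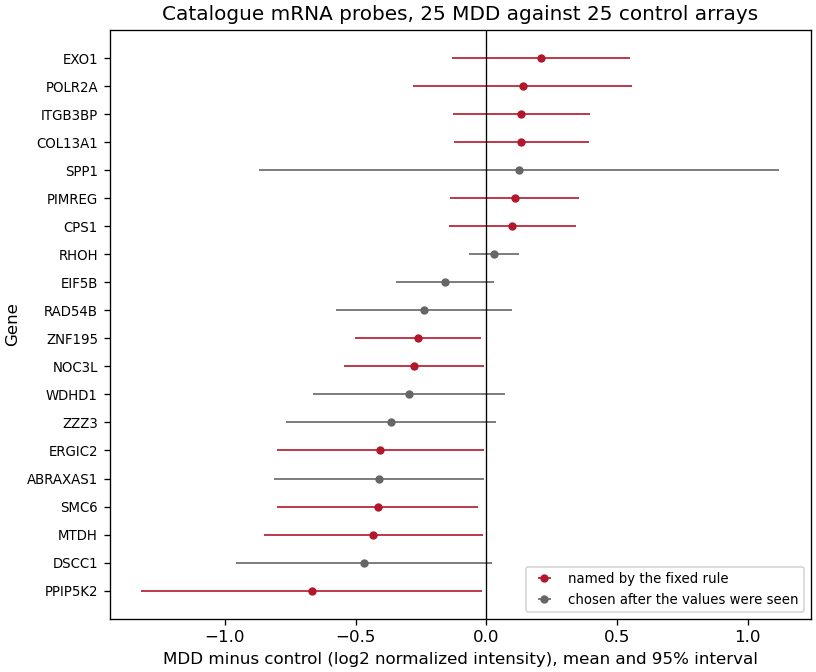
Difference between MDD and control means in log2 normalized intensity (horizontal axis) for 20 mRNA probes (vertical axis), with 95% intervals from limma over 25 arrays per group. Points in red follow the rule fixed in advance and points in grey were chosen after the values were seen; estimates run from -0.67 for PPIP5K2 to 0.21 for EXO1, and the adjusted p of every probe is at least 0.864.

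Most mRNA probes were sorted into 5 functional groups once their names were known and before their differences were examined. The groups held 11, 7, 5, 9 and 5 of the 45 tested probes and left the rest out. PPIP5K2, MTDH and ERGIC2 belonged to no group, so lower means in MDD were not confined to the groups. In the DNA replication and repair group, 10 of 11 tested members had a lower mean in MDD, and the median difference was -0.24. Its lowest member was BRCA1 at -0.50 (-0.31 with slide as a block), and its 1 higher member was EXO1 at 0.21. Besides SMC6, further members chosen after their values were seen were DSCC1 at -0.47, ABRAXAS1 at -0.41, WDHD1 at -0.30 and RAD54B at -0.24. DSCC1 acts in sister chromatid cohesion, ABRAXAS1 in the DNA damage response, WDHD1 in replication initiation and RAD54B in recombination. Over the alternatives these 4 ran from -0.67 to -0.13, -0.41 to -0.13, -0.36 to -0.067 and -0.33 to -0.075. The weakest values of DSCC1, ABRAXAS1 and WDHD1 came with normexp, whose offset shrinks the log2 differences of dim probes. WDHD1 is a dim probe that was well above background on 20 control and 12 MDD arrays. The numbers were 22 and 20 for DSCC1, 25 and 21 for ABRAXAS1, and 24 and 21 for BRCA1. In the group for transcription, chromatin and translation, 8 of 9 members were lower, with a median of -0.24. Its examples chosen likewise, besides NOC3L and ZNF195, were ZZZ3, a subunit of a histone acetyltransferase complex, at -0.36 and the translation initiation factor EIF5B at -0.16, with ranges over the alternatives of -0.45 to -0.071 and -0.19 to -0.074. Against all other tested probes, camera with a preset correlation gave an adjusted p of 0.000815 for each of these 2 groups. Both calls were lost with an estimated correlation (adjusted p = 0.117 for each). The estimates were 0.218 for replication and repair and 0.220 for transcription, far above the preset 0.01. The p-values at the preset correlation are therefore likely too small for these groups, here and under the alternatives. With slide as a block the medians were -0.29 and -0.25, with adjusted p of 0.00631 and 0.00884 at the preset correlation and adjusted p = 0.265 for both with an estimated correlation. Within slides, the median of either group was below 0 on 4 of 6 slides. Over the alternatives the median ran from -0.33 (without slide 6) to -0.079 (normexp) for DNA replication and repair and from -0.25 (slide as a block) to -0.094 (array quality weights) for transcription.

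All 45 mRNA probes as 1 set, which includes the 11 and 9 members of these groups, had a median difference of -0.12 and an adjusted p of 0.000489 at the preset correlation, and adjusted p = 0.149 with an estimated correlation. That estimate was 0.131, so the p-value at the preset 0.01 is likely too small here as well. Over the alternatives this median ran from -0.21 (without slide 6) to -0.019 (first principal component as a covariate). Set against the other mRNA probes alone, the DNA replication and repair group had an adjusted p of 0.134 and the transcription group likewise 0.134. In that test the mitosis and extracellular matrix groups, each with 4 members higher in MDD, had unadjusted p of 0.0203 and 0.0235 and an adjusted p of 0.0588 each. Array quality weights ended the preset-correlation calls of all 3 sets, with adjusted p of 0.113, 0.168 and 0.168. Leaving out slide 6 ended that of the transcription group (adjusted p = 0.0753 over 8 fewer arrays, with the median at -0.21), and the first principal component as a covariate ended that of all mRNA probes (adjusted p = 0.0624).

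For mitosis and centromere, which includes ITGB3BP and PIMREG, 3 of 7 members were lower in MDD and the median was 0.03. For immune cells, 3 of 5 were lower and the median was -0.0092. The immune group includes, chosen after their values were seen, RHOH, a small GTPase of blood cells, at 17.18 ± 0.09 in control and 17.21 ± 0.09 in MDD, and SPP1 (osteopontin, a secreted phosphoprotein made by activated microglia among other cells), at 10.47 ± 1.33 and 10.59 ± 2.20 (SD, n = 25 each). They were its 2 higher members, and its lowest was NMI at -0.098 (0.11 with slide as a block). RHOH was the brightest mRNA probe, where quantile normalization can limit the spread, so its small SD need not show a stable level. The SPP1 difference of 0.13 ran from 0.091 to 0.39 over the alternatives and was 0.33 without the 1 MDD array of lowest correlation, and the RHOH difference of 0.03 ran from 0.0079 to 0.039. For extracellular matrix and secreted liver proteins, which includes COL13A1, 1 of 5 was lower and the median was 0.03. Their adjusted p-values at the preset correlation were 0.806, 0.980 and 0.721. Each of these 3 medians changed sign under at least 1 alternative, with ranges of -0.028 to 0.15 for mitosis, -0.042 to 0.17 for immune cells and -0.0051 to 0.19 for extracellular matrix.

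Among the lncRNA probes, 0 of 6801 tested passed an adjusted p of 0.05. At an unadjusted p under 0.05 there were 152, against 340 given by chance. The 2 higher lncRNA probes with the smallest p were ASHG19SELNC2A101101311, at 3.92 ± 0.54 in control and 4.49 ± 0.60 in MDD, and ASHG19SELNC2A100804893, at 4.88 ± 0.27 and 5.33 ± 0.57 (SD, n = 25 each). Their differences were 0.57 and 0.44. The 2 lower ones were ASHG19SELNC2A100004685, at 8.13 ± 0.44 in control and 7.66 ± 0.70 in MDD, and ASHG19SELNC2A100015425, at 5.72 ± 0.29 and 5.38 ± 0.53, with differences of -0.48 and -0.34. Each of the 4 had the same direction on 6 of 6 slides and an adjusted p of 0.864. The 4 were picked by their p among 6801 probes on the same arrays, so agreement between slides is no separate support for them. Over the alternatives the differences of the higher probes ran from 0.12 to 0.74 for ASHG19SELNC2A101101311 and from 0.17 to 0.57 for ASHG19SELNC2A100804893, the lowest with normexp. Through its offset, normexp shrinks the log2 differences of dim probes. Those of the lower probes ran from -0.57 to -0.23 for ASHG19SELNC2A100004685 and from -0.41 to -0.14 for ASHG19SELNC2A100015425. ASHG19SELNC2A101101311 is a dim probe that was well above background on 16 control and 20 MDD arrays.

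As a class, 63.0% of lncRNA probes had a higher mean in MDD, compared with 42.99% of the SEP, SUPERP and TFP probes. Per array, the mean lncRNA level minus the mean level of those 3 families was -0.32 ± 0.17 in control and -0.21 ± 0.32 in MDD (SD, n = 25 each), a difference within the spread between arrays (two-sided permutation p = 0.140). Without 1 MDD array that correlated least with the others, the gap between groups was 0.06 in place of 0.11 (permutation p = 0.279). The shares for lncRNA probes and the other families were 55.8% and 43.5% without that array, and 55.9% and 49.9% without slide 6. With each array scaled to its 75th percentile, 72.6% of lncRNA probes and 53.0% of the other families were higher in MDD.

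Over the whole array, 13524 probes were tested and 0 passed an adjusted p of 0.05, the smallest adjusted p being 0.864. In limma 392 probes had an unadjusted p under 0.05, 176 higher and 216 lower in MDD, where chance gives 676 for independent probes. At an unadjusted p under 0.05 and at least 1.2-fold there were 331 probes, 127 higher and 204 lower, and at 1.5-fold or more there were 48. Without the 1 MDD array of lowest correlation these counts were 221 (105 higher) and 18. Without slide 4 they were 168 and 11, and without slide 6 they were 758 and 200. Scaling to the 75th percentile changed that balance to 235 higher among 339 probes, a share of 69.3% in place of 38.4%. Normexp gave 8 higher among 85 (9.41%) with the fold threshold, and 185 higher among 379 (48.8%, against 44.9% in the main comparison) at an unadjusted p under 0.05 alone. Estimated differences spanned -0.83 to 0.75. For 67.7% of probes the 95% interval lay within 1.5-fold in both directions, and for 95.3% it lay within 2-fold. When known differences were put into 200 of the 13524 probes of randomly relabelled arrays, a median of 87.5% were recovered at 2-fold, 46.3% at 1.5-fold and 0% at 1.2-fold over 20 draws. Probes that had not been altered were called in 8 draws at 2-fold, up to 1008 probes, in 6 draws at 1.5-fold, up to 925, and in 1 draw at 1.2-fold, with 738. Group means were removed first, labels were drawn without regard to slide, and each altered probe moved by the same fold on every relabelled array. Recovery in the real layout, where slide 6 held MDD arrays only, may therefore differ.

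**Figure D2:**
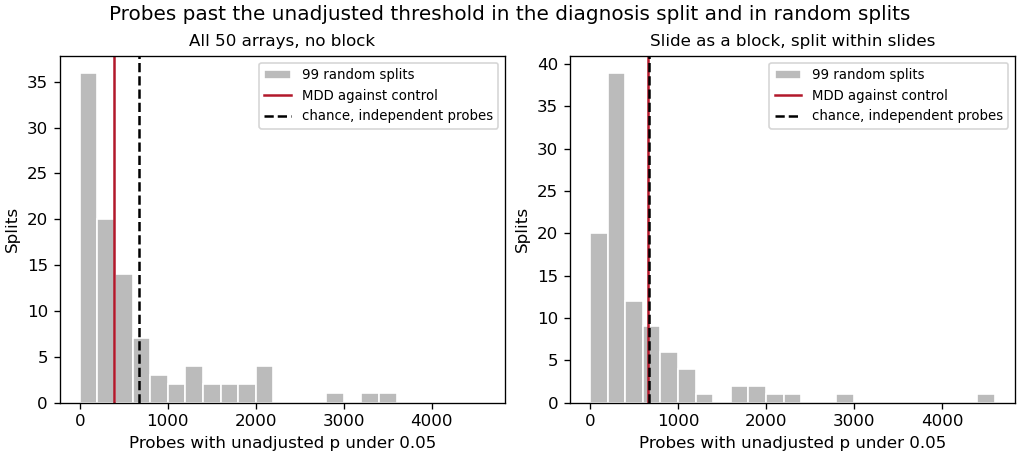
Number of probes with an unadjusted p under 0.05 (horizontal axis) in 99 random splits of the 50 arrays (grey bars, vertical axis counts splits), for MDD against control (red line) and as chance gives for independent probes (dashed line). Without a block the diagnosis split gave 392 probes and the median random split 328; with slide as a block and splits drawn within slides the values were 664 and 316.

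Slides separated the arrays more than diagnosis did. The arrays fell on 7 slides, of which 6 held both groups and slide 6 held 8 MDD arrays only. For the median probe 44.02% of the variance lay between slides, where chance gives 12.2%, and 1.22% between the diagnosis groups, where chance gives 2.04%. Between slides 9874 probes differed at an adjusted p under 0.05, including 28 of the 45 mRNA probes. With slide as a block, 0 probes passed for MDD against control, 664 had an unadjusted p under 0.05 (325 higher, 339 lower), and the smallest adjusted p was 0.799. Within each of the 6 slides with both groups, 0 probes passed, and from 74 to 1763 had an unadjusted p under 0.05. These slides held only 2 to 4 MDD and 3 to 5 control arrays each, so that 0 carries little weight.

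**Figure D3:**
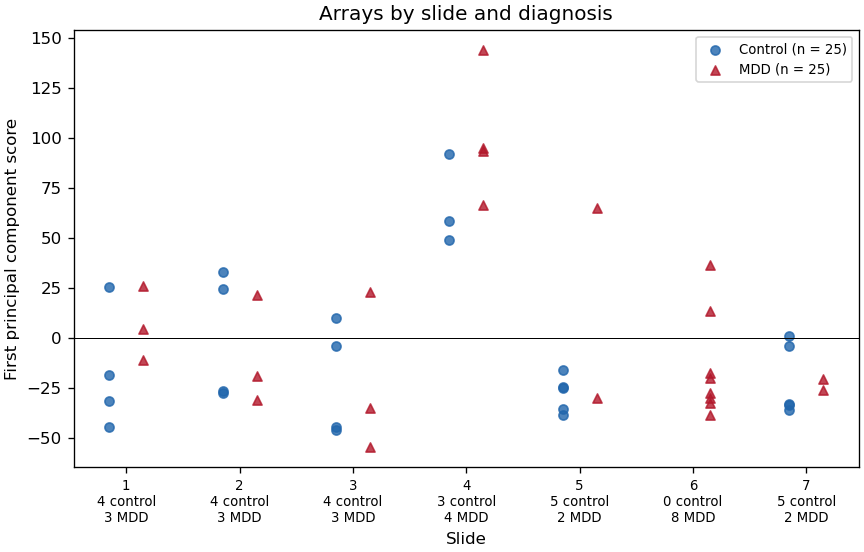
First principal component score of each array (vertical axis, no unit) by slide (horizontal axis), with circles for control and triangles for MDD arrays. The 3 control arrays of slide 4 lie between 48.9 and 92.3 and its 4 MDD arrays between 66.7 and 144, while on the other slides control arrays lie between -45.9 and 33.0 and MDD arrays between -54.8 and 65.2.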

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

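In this part, the comparison of the slide 4 control arrays with the others and the slide-block count were chosen only after the result was seen. No class of spots outside the comparison passed a two-sided test between the groups. Custom, spike-in, negative-control and other control spots were set against control arrays on log2 signal relative to each array's 75th percentile, and the smallest adjusted permutation p of the 6 classes was 0.181. The custom spots differed by -0.25 between MDD and control, and the other 5 classes were higher in MDD by 0.25 to 0.41, with 0.39 for the negative controls.

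The 7 arrays of slide 4 scored high on the first principal component, from 48.9 to 144, and that component held 29.0% of the variance. The other slides ran from -54.8 to 65.2, so the ranges overlapped, through 1 MDD array. Diagnosis does not account for the high scores of slide 4, since the lowest score among the 3 control arrays of slide 4 was 48.9 and the highest among the other control arrays was 33.0. Raised background remains a candidate explanation. The negative-control probes of slide 4 had a median normalized log2 value of 5.34, above the 4.07 to 4.56 of the other slides. Subject differences other than diagnosis were not tested.

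In the main comparison, fewer probes passed an unadjusted p of 0.05 than the 676 that chance gives for independent probes. With slide as a block the number was 664, and without the 1 MDD array of lowest correlation it was 287. Random splits of the same arrays without a block gave from 36 to 3476 probes, with a median of 328, so a count under 676 is common for these correlated probes. Against the 392 of the main comparison, the count moved toward 676 with slide as a block and away from 676 without the outlying array. The move without that array is opposite to what it would give as the explanation. Because the spread of the splits reaches past 676, neither count settles the question. Of 100 splits, 44 gave at least as many probes as diagnosis did. The shortfall did not hold under every setting. Without slide 6, which held MDD arrays only, 801 probes passed, and with array quality weights 1013 did. Under the other alternatives the count stayed below the number that chance gives for the probes tested.

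More probes had a larger spread among MDD than among control arrays, 79.3% of those tested. Chance is not excluded, because 18 of 100 splits gave as large a share in either direction and the highest other split gave 89.2%. Without the MDD array of lowest correlation (median correlation 0.786, next lowest 0.852) the share was 67.6%. Of 100 splits of the remaining arrays, 36 gave as large a share in either direction, with 86.2% in the highest other split, so the part played by that array cannot be told apart from chance. A wider biological range among MDD subjects stays open as well and was not tested.

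Chance could not be excluded for the counts of probes at an unadjusted p. For probes past an unadjusted p of 0.05 and 1.2-fold, 43 of 100 splits gave at least 331, with 3188 in the highest other. For probes past an unadjusted p of 0.05 with slide as a block, 25 of 100 splits within slides gave at least 664, with 4439 in the highest other. At the adjusted threshold the diagnosis split gave 0 probes, so 100 of 100 splits necessarily gave at least as many, and these splits say nothing about chance. The highest other split gave 204 probes, of them 114 lncRNA and 0 mRNA probes, and 2 of 99 other splits gave any. Splits that call several times the diagnosis count point to variation shared among arrays, whose source these counts do not identify.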

How the results depend on the processing

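Settings that left out slide 4, slide 6 or the array of lowest correlation were chosen after seeing the data. Under the 15 alternatives, 0 probes passed an adjusted p of 0.05, lncRNA and mRNA probes included, with the smallest adjusted p between 0.208 (array quality weights) and 0.989 (first principal component). The count at an unadjusted p under 0.05 ranged from 208 to 1013. The authors' table holds none of the catalogue mRNA probes and gave no value for them. The count past an unadjusted p of 0.05 and 1.2-fold moved from 331 to 85 with normexp, 151 with probes well above background on all 50 arrays, 613 with array quality weights, 164 with the first principal component, 168 without slide 4, 758 without slide 6 and 48 at 1.5-fold. Fewer probes were tested under the stricter filter, and the 1.5-fold count is a part of the 1.2-fold count. With normexp the count at an unadjusted p under 0.05 alone was 379 against 392, so its fall came with the fold threshold. Median signals ran from 31.6 to 217 over the arrays, so its offset of 50 shrinks many log2 differences. Smaller differences with normexp are therefore not by themselves a sign of a less stable estimate. The cause was not tested for the rest. With the subject number as a replicate block the count was 474 and 0 probes passed the adjusted threshold. Same-numbered arrays showed little likeness, since 8 of 25 pairs correlated above 0.1 and 0 MDD arrays correlated best with their own number. That check cannot exclude matched subjects, because 4 of the 25 pairs shared a slide and slide differences could hide a match. The difference in detection turned to 0.0536 percentage points within slides and to 0.624 without slide 6, with p of 0.967 and 0.665. The differences of PPIP5K2, SMC6, ERGIC2, MTDH, NOC3L and ZNF195 were all smaller with array quality weights. Of 332 values of 24 named probes, BRCA1 and NMI not among them, 328 kept their direction. The exceptions were COL13A1 at -0.023 (slide block), PIMREG at -0.0038 and POLR2A at -0.094 (array quality weights), and POLR2A at -0.054 (first principal component). The immune group's median turned to 0.014 with 75th percentile scaling, 0.023 with normexp, 0.11 with slide and 0.17 with scan day as a block, 0.071 with array weights, 0.0079 with the first principal component, 0.026 without the array of lowest correlation, 0.022 without slide 4 and 0.066 without slide 6. The mitosis group's turned to -0.0019 with array weights, -0.016 without that array and -0.028 without slide 6, and the extracellular matrix group's to -0.0051 with slide as a block. The cause was not tested for these. Signal over background limits the dimmest probes, of which 1319 were not tested.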

Other observations

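The values in this part were chosen after the result was seen. Of the identifier families, the share of probes with a higher mean in MDD was 63.3% for SELNC, 51.4% for SUPERLNC, 42.8% for SEP, 45.1% for SUPERP and 40.8% for TFP. With slide as a block the shares were 60.6%, 55.6%, 47.1%, 51.9% and 44.1%. Within the 6 slides with both groups, most probes were higher in MDD on 3 slides for SELNC, SUPERLNC and SUPERP and on 1 for SEP. For TFP this held on 0 slides, though its share of higher probes ran from 43.8% to 49.9%, close to even on the highest slide. Under 75th percentile scaling 53.0% of SEP, SUPERP and TFP probes were higher in MDD.

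Slides also differed in detection and in signal range. The mean share of probes well above background ran from 85.4% on slide 7 to 93.4% on slide 3. The distance from the median to the 75th percentile of signal was 1.28 log2 on slide 4 and 1.80 to 2.06 on the other slides.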
